A study of Homo sapiens with 19 samples.

How the data were processed

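RNA was sequenced from whole cells and from subcellular fractions of K562, an established human erythroleukaemia cell line. The series holds 19 libraries in 5 groups. Whole cell, cytoplasm, nuclear wash and nucleus had 4 libraries each, and the nuclear wash was prepared a second time without rRNA depletion in 3 libraries. The labels number the replicates 1 to 4 within a fraction, and the column names carry the prefixes 1A, 1B, 2B and 2C for replicates 1, 2, 3 and 4. The 3 undepleted libraries carry the prefixes 1B, 2B and 2C, so their replicate numbers 1, 2 and 3 do not match those of the depleted wash. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, RNA was extracted with Trizol LS, synthetic yeast transcripts were added as spike-ins, and stranded total RNA libraries were made with a SMARTer kit that removes rRNA, a step left out for the undepleted wash.

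The authors deposited a pair of count tables with one column per library, and the values in both are raw read counts per gene, with no normalization. One table holds counts over exons for 58051 human genes and 11 yeast transcripts, and the other holds counts over whole gene bodies for the same human genes. The submitters' processing notes name cutadapt 2.5, STAR 2.7.0a, featureCounts 1.6.2 and the genome build hg38, without saying what each was set to. The annotation release, the strand setting of the counting and the handling of reads shared between genes are not given in the sources used here. Values of overlapping, antisense and multi-copy genes are therefore uncertain where they are printed. Gene symbols, positions and exon lengths were taken from GENCODE release 29 on GRCh38, the assembly also called hg38, in which 57447 of the 58051 identifiers were found by exact match. Every count column matched one library, and 0 columns were left unused.

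Exon counts per library ranged from 1373755 to 7955415 in the depleted libraries and from 923464 to 1801293 in the undepleted ones. Gene-body counts ranged from 4274729 to 11384115 and from 1107400 to 2022408. The spike-in transcripts, which took 0.192 to 4.14% of the exon counts, were left out of library sizes and tests. The labels do not say how much spike-in was added to which amount of sample, per cell or per RNA, so values scaled by spike-ins, given as an alternative, cannot be read as amounts of RNA. Reads were counted without molecular identifiers as far as the labels state, so PCR copies cannot be separated from molecules.

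Differential abundance was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the exon counts. The 16 depleted libraries entered a single fit with one term per fraction, so that all contrasts shared one estimate of the spread, and the 7 wash libraries entered a separate fit for the comparison of undepleted with depleted wash. Genes were kept by filterByExpr with the groups given, which left 15940 and 11627 genes. Libraries were scaled by TMM, which sets the typical gene to no change, so fold changes are relative to that gene and not to the amount of RNA in a fraction. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are read counts scaled to a common library size, computed here with the TMM factors, given as mean ± SD over libraries. A gene was called higher or lower in the wash than in both cytoplasm and nucleus by an intersection-union test, which takes the larger of the p-values of both contrasts where both fold changes have the same sign, adjusted over all genes.

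Gene lists, 20 in number, were written from textbook knowledge of cell compartments and of K562 before the data were examined, together with the tests, the groups, the alternatives and the rule for naming genes. Lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists of a comparison. Camera was repeated with the correlation estimated from the data, and fry was run on the same lists. For each list, members past the threshold were counted both over all genes tested and with p-values adjusted over the list alone. Genes are named by a rule. For each main comparison it takes the 6 genes with the largest fold change in each direction among called genes with a mean of at least 10 CPM whose libraries do not overlap between groups. It also takes, per list, the 2 called members with the largest change in the main direction and the 1 with the largest change the other way at a mean of at least 5 CPM, and the landmarks MALAT1, NEAT1, GAPDH, ACTB, HSPA5, TFRC, RPLP0, MT-CO1, GATA1 and HBG1. For the joint test it takes the 10 called genes with the largest smaller fold change, and for the comparisons with whole cells the 3 largest in each direction. Only genes with a symbol were named, and not all genes that the rule gives are printed.

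The intronic share of a library was computed as 1 minus the summed exon counts over the summed gene-body counts, over 52317 genes that are not mitochondrially encoded and whose gene-body counts, summed over libraries, were at least their exon counts. The mitochondrial share is the exon counts on the 13 mitochondrially encoded mRNAs over all exon counts outside rRNA genes. Shares were compared by two-sided exact permutation tests of the difference of means, adjusted over the 6 pairs of depleted fractions. With 4 libraries against 4 there are 70 regroupings, and the smallest p that can be reached is 0.0286. Wash and whole-cell libraries were fitted as non-negative least squares mixtures of the mean CPM profiles of the other fractions, weighted by 1 over the mean CPM plus 1, without mitochondrial and rRNA genes. NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used under Python for these steps and the plots.

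Whether replicate numbers pair the libraries was checked by correlating deviations from the group means. All 24 same-numbered pairs of depleted libraries from different fractions had correlations over 0.1, from 0.104 to 0.379, with a median of 0.196. The main fits hold no term for the number or the prefix. Fits with the number as a block were compared with them as an alternative. Pairs with different numbers but the same first character of the prefix had a median correlation of 0.202, against -0.208 for pairs whose first characters differ, and 10 of 16 libraries correlated best with their own number. The shared part is therefore mostly between the libraries of prefixes 1A and 1B on one side and those of 2B and 2C on the other. By these medians the number adds no pairing beyond the first character of the prefix. The undepleted and depleted wash libraries of the same prefix correlated at 0.214 to 0.465.

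The methods were tested on simulated data. With 200 genes changed in counts drawn from the real means, spreads and library sizes, the nucleus and cytoplasm comparison over 15201 genes recovered 62.1% of 2-fold and 87.1% of 4-fold changes and called 10 unchanged genes. The comparison of the wash libraries over 11248 genes recovered 42.9% and 94.7%, and called 11 unchanged genes. Camera called the changed list in both cases and none of 19 random lists. Genes were drawn independently of each other, so false calls on lists with correlated members were not tested. All other genes had the same mean in every group, whereas 76.8% of genes were called between the real nucleus and cytoplasm. False calls from scaling when most genes differ were therefore not tested either. The mixture fit returned 29.1% for a set nuclear weight of 30% and 60.8% for 60%. These libraries were drawn from the same mean profiles that were then fitted. A wash with RNA beyond such a mixture, as its 23.28% of variance left allows, was not tested. Alternatives tried were RLE factors, no composition factor, spike-in library sizes, other low-count filters, gene-body counts, DESeq2 1.42.0, a replicate block, fits of only the groups compared, leaving out each library, and leaving out mitochondrial and rRNA genes. Fits within the libraries of prefix 1 and of prefix 2 were added after the data had been seen.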

Results

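Total RNA was sequenced from K562, a human erythroleukaemia line that expresses fetal globins. Whole cells and 3 fractions were measured, the cytoplasm, the nucleus and a nuclear wash. Each of these 4 groups had 4 libraries depleted of rRNA, and the nuclear wash was also sequenced in 3 libraries without depletion. Depleted libraries held 1373755 to 7955415 exon counts, and undepleted ones 923464 to 1801293. Mitochondrial 16S rRNA (MT-RNR2) took 4.92 to 26.2% of the exon counts of depleted libraries and 24.2 to 36.5% of those of undepleted ones. Column names split the libraries into replicates 1 and 2 (prefix 1) and replicates 3 and 4 (prefix 2), and values within each prefix are given for shares, for counts of genes called and for named genes whose values differed between them.

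Intronic RNA differed between all fractions. Intronic counts made up 75.0% ± 2.19 (SD, n = 4) of gene-body counts in the nucleus and 51.5% ± 3.71 in whole cells. They made up 28.4% ± 3.44 in the nuclear wash and 16.6% ± 1.39 in the cytoplasm, and 23.5% ± 2.97 (n = 3) in the undepleted wash. The nucleus exceeded the cytoplasm by 58.37 percentage points and the wash exceeded the cytoplasm by 11.83, with no overlap between the libraries of either pair. Each difference had p = 0.0286 and adjusted p = 0.0286 in a two-sided exact permutation test, the smallest that 4 libraries against 4 can give. All 6 pairs of depleted fractions differed at that p. That test ignores the replicate numbers. In each of the 6, all 4 same-numbered pairs of libraries went the same way. Any other pairing would do so too, since the libraries of different fractions did not overlap. An exact paired permutation test, added after the counts had been seen, gave p = 0.125 each, the smallest that 4 pairs can give. The wash held 29.7 and 32.7% in the libraries of prefix 1 and 25.8 and 25.5% in those of prefix 2, against 17.7, 17.9, 15.3 and 15.6% in the cytoplasm.

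As a share of exon counts, mitochondrially encoded mRNAs were highest in the wash. The 13 mitochondrially encoded mRNAs took 7.82% ± 0.942 (SD, n = 4) of exon counts outside rRNA genes in the nuclear wash and 12.3% ± 2.72 (n = 3) in the undepleted wash. Their share was 4.52% ± 0.953 in the cytoplasm, 4.23% ± 0.36 in whole cells and 1.75% ± 0.453 in the nucleus. The wash exceeded the nucleus by 6.07 points, the cytoplasm by 3.29 and whole cells by 3.59 (exact permutation test, adjusted p = 0.0343 each). It was higher in all 4 same-numbered pairs each time, as in any other pairing, since its libraries did not overlap with theirs. There the exact paired permutation test gave p = 0.125, the smallest that 4 pairs can give. Cytoplasm and whole cells differed by 0.29 points, which did not pass (exact permutation test, adjusted p = 0.686) but did so with gene-body counts, by 1.71, and with mitochondrial rRNA included, by 3.78 (exact permutation test, adjusted p = 0.0343 each). With gene-body counts the wash exceeded the cytoplasm by 2.00 points (exact permutation test, adjusted p = 0.0571) and with mitochondrial rRNA included by 4.28 (exact permutation test, adjusted p = 0.143), so neither setting kept that difference past the threshold. Gene-body totals include intronic counts, at 51.5% in whole cells, 28.4% in the wash and 16.6% in the cytoplasm outside mitochondrial genes. The differences with gene-body counts therefore also carry that of the intronic share and are no independent check. The wash held 8.21 and 6.41% in the libraries of prefix 1 and 8.19 and 8.45% in those of prefix 2, against 3.62, 3.99, 4.68 and 5.79% in the cytoplasm.

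**Figure D1:**
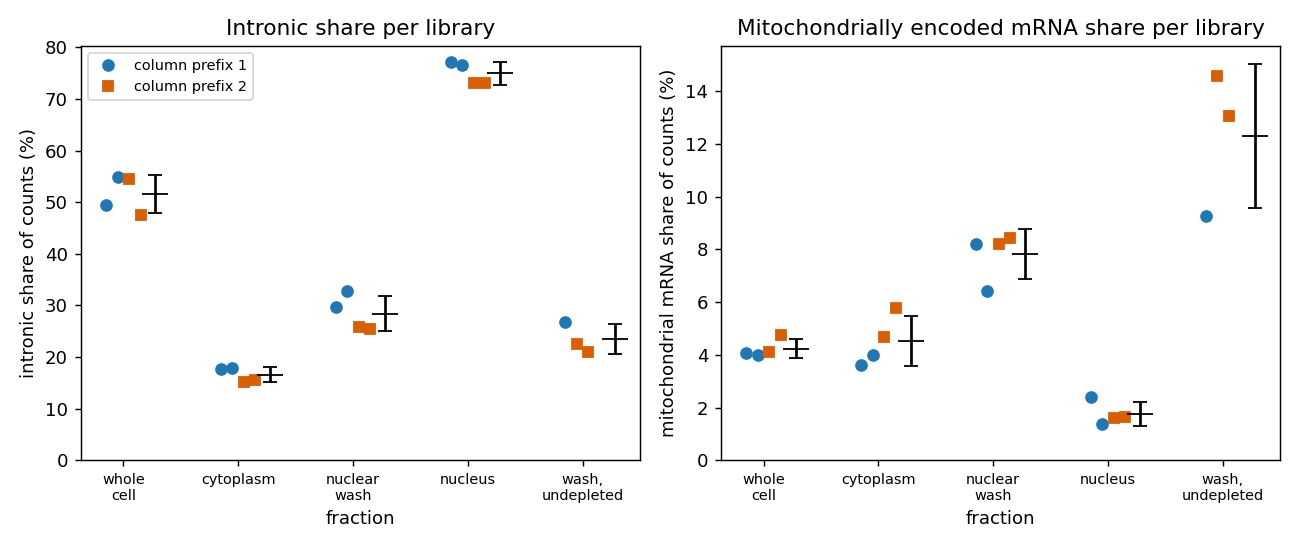
Percent of gene-body counts that were intronic and percent of exon counts on the 13 mitochondrially encoded mRNAs, per library of each group, with circles for column prefix 1, squares for prefix 2, and bars for mean ± SD. The 4 nuclear libraries lie at 73.0 to 77.1% intronic and the 4 wash libraries at 25.5 to 32.7%, while the mitochondrial share has its lowest mean in the nucleus (1.75%) and its highest in the undepleted wash (12.3%).

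Nucleus and cytoplasm were compared first. MALAT1, a long noncoding RNA of nuclear speckles, was at 59390 ± 9880 CPM in the nucleus and 3147 ± 411 in the cytoplasm (log2 fold change 4.24, SE 0.369, n = 4 per group, adjusted p = 1.4e-09). NEAT1, the scaffold of paraspeckles, was at 1543 ± 138 against 209.8 ± 9.35 CPM (2.88, adjusted p = 1.23e-13). KCNQ1OT1, an imprinted RNA transcribed antisense to KCNQ1, was higher in the nucleus by 4.96 and the small nucleolar RNA host gene GAS5 by 3.26. The reverse held for GAPDH, a glycolytic enzyme, at 136.0 ± 6.43 against 1886 ± 215 CPM (-3.79, SE 0.134, adjusted p = 6.77e-15), and for the cytoskeletal actin ACTB at 288.6 ± 9.55 against 2630 ± 113 (-3.19, SE 0.108, adjusted p = 4.47e-15). The fetal globin HBG2 was at -3.56, an uncertain value since its annotated span overlaps other genes, HBE1 among them. Mitochondrially encoded MT-CO1, a cytochrome c oxidase subunit, was at 2397 ± 728 against 11960 ± 585 CPM (-2.32, adjusted p = 1.29e-10), and MT-CO2 was at -2.91.

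Several of the genes with the greatest nuclear excess lie inside other genes. FRMD5, a protein-coding gene (ENSG00000171877, GRCh38 chromosome 15, 43870761 to 44195252), was at 64.35 ± 6.02 CPM against 0.7064 ± 0.167 (6.45, SE 0.284, adjusted p = 8.07e-14), and OR2B2 was at 6.33. OMD was at 6.73, LINC01028 at 6.55, TMEM14EP at 6.42 and OR51B6 at 5.94, and since these 4 overlap other genes their counts are uncertain. Lower in the nucleus were RN7SL2, a 7SL RNA of the signal recognition particle (-5.32), the histone gene H4C3 (-4.88), RPL35 (-4.22) and RPS2 (-4.15, with -3.62 within prefix 1 and -4.67 within prefix 2). Their families hold near-identical copies, so these values are uncertain too. MALAT1 is annotated at chromosome 11, 65497688 to 65506516 (ENSG00000251562), and GAPDH at chromosome 12, 6533927 to 6538374 (ENSG00000111640).

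Of 79 cytosolic ribosomal protein mRNAs, 76 were lower in the nucleus and 3 higher, with the same numbers adjusted over the list alone. Their median log2 fold change was -2.82 (camera adjusted p = 1.18e-19, and adjusted p = 0.0978 with an estimated correlation). RPL36A, which shares a locus with a read-through gene, was the highest of the 3 exceptions at 3.29. Replication-dependent histone mRNAs were lower in 42 of 45, at a median of -3.17 (camera adjusted p = 9.27e-13, and adjusted p = 0.0449 with an estimated correlation). Cytosolic chaperone and cytoskeleton mRNAs were lower in 33 of 34, at a median of -2.10 (camera adjusted p = 3.2e-11, and adjusted p = 0.0449 with an estimated correlation). Both lists gave the same numbers adjusted over the list alone. Translation factor mRNAs were lower in 28 of 33, EIF5A at -3.63 among them, also adjusted over the list alone (camera adjusted p = 1.17e-08, and adjusted p = 0.0449 with an estimated correlation).

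Respiratory, erythroid and short-lived mRNAs were also lower in the nucleus. Of 74 nuclear-encoded oxidative phosphorylation mRNAs 59 were lower and 7 higher, also adjusted over the list alone, at a median of -1.75 (camera adjusted p = 2.48e-09, and adjusted p = 0.13 with an estimated correlation). UQCR10 was at -3.42, while NDUFV2 was higher at 4.12. Of 41 erythroid and megakaryocytic mRNAs 31 were lower and 5 higher, also adjusted over the list alone, at a median of -1.28 (camera adjusted p = 2.07e-05, and adjusted p = 0.0806 with an estimated correlation). The erythroid transcription factor GATA1 was at -2.13. Immediate early and other short-lived mRNAs were lower in 28 of 38 and higher in 2, or 29 and 2 adjusted over the list alone (camera adjusted p = 0.0018, and adjusted p = 0.218 with an estimated correlation). JUND was at -2.80, and MYB, a transcription factor of progenitors, was higher at 0.38 but at -0.25 with library sizes from the spike-ins. Of the 13 mitochondrially encoded mRNAs 10 were lower and 2 higher, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00378, and adjusted p = 0.427 with an estimated correlation).

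Nuclear long noncoding RNAs were higher in 10 of 15 and lower in 3, or 10 and 4 adjusted over the list alone. Their median was 2.69 (camera adjusted p = 0.023, adjusted p = 0.218 with an estimated correlation, and 0.0929 with gene-body counts). Among 44 mRNAs of RNA-binding proteins known for regulated intron retention, 32 were higher and 7 lower, also adjusted over the list alone. That list had a median of 1.25 (camera adjusted p = 6.04e-05, and adjusted p = 0.216 with an estimated correlation), and counts over whole gene bodies ended the call (camera adjusted p = 0.966). NKTR, a cyclophilin with an arginine-serine domain, was at 1054 against 86.21 CPM (3.61), CCNL2, a speckle cyclin, at 3.11, and HNRNPK was lower at -1.53. Of 66 zinc finger protein mRNAs 40 were higher and 9 lower, or 40 and 8 adjusted over the list alone, at a median of 0.65 that was 0.02 with spike-in library sizes (camera adjusted p = 0.0063, and adjusted p = 0.218 with an estimated correlation). ZNF154 was at 4.10. Small nuclear and other structured noncoding RNAs were higher in 10 of 14 and lower in 3, also adjusted over the list alone (camera adjusted p = 0.0754, 0.037 with the replicate number as a block, and adjusted p = 0.553 with an estimated correlation), with SNORA73B, which lies inside its host gene, at 4.19.

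mRNAs of the endoplasmic reticulum were lower in 40 of 62 and higher in 11, also adjusted over the list alone, at a median of -0.65 (camera adjusted p = 0.00117, and adjusted p = 0.218 with an estimated correlation). Without a composition factor 24 were higher and 22 lower, at a median of -0.05. DAD1, an oligosaccharyltransferase subunit, was at -3.51, while HSPA5, the lumenal chaperone BiP, was at 0.48 (adjusted p = 0.00959). edgeR's quasi-likelihood test called 12236 of 15940 genes, 6266 higher in the nucleus and 5970 lower, 4868 and 4067 of them by at least 2-fold. Within the libraries of prefix 1 and of prefix 2 it called 11272 and 12280. Higher calls were 51.2% of the calls, 69.3% without a composition factor, 63.2% with DESeq2 and 34.7% with spike-in library sizes. The labels do not give how much spike-in went into how much sample, so what spike-in scaled values measure is open here and in each comparison. The median log2 fold change of all genes was 0.02, and it was 0.63 without a factor, 0.16 with RLE factors and -0.6 with spike-ins. HSPA5 was at -0.12 and TFRC, the transferrin receptor, at 0.17 instead of 0.84 with spike-ins. With gene-body counts HSPA5 was at -0.96, TFRC at 0.03 and HBG1 at 2.56 instead of -1.93. HSPA5 was not called without cytoplasm replicate 2 (0.37, adjusted p = 0.0553), nor MYB without the low-count filter (0.23). MT-ND3, at 0.81 (adjusted p = 0.000316), was at 1.43 within prefix 1 in a test of the difference, not called within prefix 2 alone (0.24, adjusted p = 0.0716), and at -0.69 with gene-body counts.

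**Figure D2:**
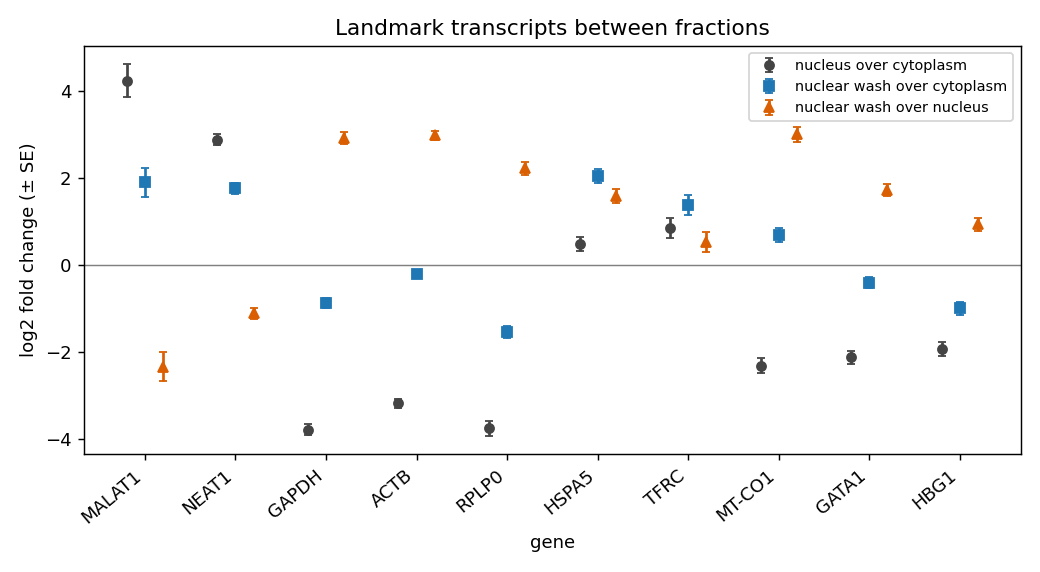
Log2 fold change of 10 landmark genes for nucleus over cytoplasm, nuclear wash over cytoplasm and nuclear wash over nucleus, with points for the estimate relative to the typical gene and bars for ± 1 SE (4 libraries per group). MALAT1 lies at 4.24, 1.90 and -2.34 and GAPDH at -3.79, -0.88 and 2.92, and with library sizes from the spike-ins the median gene of the wash over cytoplasm lies at -3.1, which turns MALAT1 (-1.17), NEAT1, HSPA5 (-1.13), TFRC and MT-CO1, and that over nucleus at -2.47, which turns HSPA5 (-1.01), TFRC, GATA1 and HBG1.

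Nuclear wash and cytoplasm were compared next. SPTBN1, beta spectrin (ENSG00000115306, chromosome 2, 54456285 to 54671445), was at 737.5 ± 142 CPM in the wash and 42.43 ± 10.9 in the cytoplasm (log2 fold change 4.12, SE 0.171, n = 4 per group, adjusted p = 3.94e-13). SPTAN1, alpha spectrin, was at 3.81, and DBN1, the actin-binding drebrin, at 3.52. IQGAP1, a scaffold of actin and small GTPases, was at 643.8 ± 125 CPM against 42.01 (3.94), with log2 fold changes of 4.29 within prefix 1 and 3.56 within prefix 2. HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330) was at 1305 ± 209 against 315.3 ± 63.5 CPM (2.05, SE 0.163, adjusted p = 5.35e-09). On the other side RPLP0, a ribosomal stalk protein (ENSG00000089157, chromosome 12, 120196686 to 120201235), was at 511.9 ± 113 against 1496 ± 129 CPM (-1.55, SE 0.147, adjusted p = 5.71e-08). GPX4, a glutathione peroxidase, and MZT1, a spindle organizer, were both at -1.65. All these values are relative to the typical gene. With library sizes from the spike-ins the median gene was at -3.1, SPTBN1 at 0.97, IQGAP1 at 0.81, HSPA5 at -1.13 and RPLP0 at -4.75, and DBN1 was no longer called (0.39).

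mRNAs translated at the endoplasmic reticulum were higher in 46 of 62 and lower in 5, or 47 and 5 adjusted over the list alone, although with spike-in library sizes all 62 were lower at a median of -2.01. The main median was 1.16 (camera adjusted p = 9.18e-18, and adjusted p = 0.017 with an estimated correlation). HYOU1, a chaperone of the lumen, was at 2.00, and OST4, a small subunit of the oligosaccharyltransferase, was lower at -0.97. Plasma membrane and lysosomal protein mRNAs were higher in 42 of 45, also adjusted over the list alone, and lower in all 45 with spike-in library sizes at a median of -1.86. Here the main median was 1.34 (camera adjusted p = 9.18e-18, and adjusted p = 0.017 with an estimated correlation). IGF2R, the mannose 6-phosphate receptor, was at 2.12, APLP2, a membrane protein of the amyloid precursor family, at 2.12 and TFRC at 1.37 (adjusted p = 5.75e-05). GYPC, a glycophorin of red cells, was the exception at -1.04. Of markers of other cell types 3 of 3 lymphoid, 2 of 3 epithelial and 4 of 4 fibroblast or endothelial ones were higher, with the same numbers adjusted over the list alone except that 1 epithelial marker was then lower. With spike-in library sizes all were lower. Among them were PTPRC, a leukocyte phosphatase, at 1.61, EPCAM, an epithelial adhesion protein, at 1.36, COL1A2, a collagen, at 2.54 and FN1, fibronectin, at 2.19. These 4 genes encode membrane or secreted proteins.

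Ribosomal protein mRNAs were lower in the wash than in the cytoplasm in 73 of 79 and higher in 1, or 74 and 1 adjusted over the list alone. Their median was -1.05 (camera adjusted p = 1.87e-24, and adjusted p = 0.0574 with an estimated correlation), with RPS2 at -1.72 and RPL12 at -1.62. Translation factor mRNAs were lower in 23 of 33, also adjusted over the list alone, at a median of -0.65 (camera adjusted p = 1.92e-08, and adjusted p = 0.017 with an estimated correlation). TPT1 was at -1.49 and EEF1A1, the elongation factor, at -1.09. Histone mRNAs were lower in 40 of 45, or 41 adjusted over the list alone, at a median of -1.07 (camera adjusted p = 1.83e-13, and adjusted p = 0.0306 with an estimated correlation), H4C3 at -1.54. Of 74 oxidative phosphorylation mRNAs of the nuclear genome 36 were lower and 4 higher, or 36 and 5 adjusted over the list alone (camera adjusted p = 3.57e-05, and adjusted p = 0.346 with an estimated correlation). Cytosolic chaperone and cytoskeleton mRNAs were lower in 13 of 34, also adjusted over the list alone, and 19 were not called (camera adjusted p = 0.0164, and adjusted p = 0.433 with an estimated correlation). FLNA, a filamin, was higher at 1.13 but at -2.02 with spike-in library sizes. ACTB was at -0.21 (adjusted p = 0.0842), and was called with DESeq2 (adjusted p = 0.0012), with gene-body counts (-0.57) and without mitochondrial and rRNA genes (-0.25).

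Of the 13 mitochondrially encoded mRNAs 6 were higher in the wash and 7 not called, also adjusted over the list alone, whereas 12 were lower with spike-in library sizes. The camera call (adjusted p = 0.00168) was lost with gene-body counts (adjusted p = 0.0846) and had adjusted p = 0.435 with an estimated correlation. MT-ND6, encoded on the light strand, was at 2.79, and the mitochondrial tRNA gene MT-TN at 3.71. MT-ND3 was at 2.78, with 3.21 within prefix 1 and 2.43 within prefix 2. MT-CO1 was at 0.68 (adjusted p = 0.00222) but was not called with gene-body counts (0.33) or within prefix 1 (0.52, adjusted p = 0.0904). Intron-retaining RNA-binding protein mRNAs were higher in 26 of 44 and lower in 2, or 27 and 2 adjusted over the list alone, while all 44 were lower with spike-in library sizes. That list had camera adjusted p = 1.51e-05, adjusted p = 0.222 with an estimated correlation and 0.097 with gene-body counts. SRRM2, a speckle protein, was at 1.95 and the splicing factor ARGLU1 at 2.08, with 2.55 within prefix 1 and 1.52 within prefix 2. MALAT1 was at 11710 ± 8230 CPM against 3147 (1.90, adjusted p = 0.000113), with 2.47 within prefix 1 and 0.72 within prefix 2, and NEAT1 was at 1.76. Nuclear long noncoding RNAs as a list were higher in 7 of 15 and lower in 5, also adjusted over the list alone, which did not pass (camera adjusted p = 0.0781, and adjusted p = 0.433 with an estimated correlation) except with gene-body counts (0.0445).

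edgeR called 7053 of 15940 genes between wash and cytoplasm, 3638 higher in the wash and 3415 lower, but 2148 against 655 at 2-fold or more. Within prefix 1 it called 6085 genes and within prefix 2 6391. With library sizes from the spike-ins 3 genes were higher and 14866 lower, so the 51.6% of higher calls holds only relative to the typical gene. GATA1 (-0.42, adjusted p = 0.0133) was not called without the low-count filter (-0.34), within prefix 2 (-0.11) or in a fit of these 2 groups alone (-0.35), and HBG1, at -1.01, turned to 1.85 with gene-body counts.

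Nuclear wash and nucleus were compared next, again relative to the typical gene. GAPDH was at 1027 ± 86.9 CPM in the wash against 136 ± 6.43 in the nucleus (log2 fold change 2.92, SE 0.129, n = 4 per group, adjusted p = 9.49e-13), and ACTB at 2269 ± 106 against 288.6 ± 9.55 (2.97, SE 0.107, adjusted p = 6.23e-14). The adult globin HBA2 was at 3.60 and RN7SL2 at 3.64. Lower in the wash were the noncoding RNAs KCNQ1OT1 at -3.11, GAS5 at -2.56, NEAT1 at -1.12 and MALAT1 at -2.34 (SE 0.34, adjusted p = 3.6e-06). MALAT1 was at -1.87 within prefix 1 and -3.39 within prefix 2. FRMD5 was at -3.99 and OR2B2 at -4.05, while NORAD, a mostly cytoplasmic noncoding RNA, was higher at 1.93. The median gene was at 0.06, at -2.47 with spike-in library sizes and at -0.6 without a composition factor, so positive values are again relative to the typical gene. With spike-ins GAPDH was at 0.38 and not called (adjusted p = 0.0589) and NORAD at -0.59. With gene-body counts NEAT1 was at 0.004.

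Ribosomal protein mRNAs were higher in the wash than in the nucleus in 71 of 79, RPL35 at 2.89, but lower in 57 with spike-in library sizes. Their median was 1.76 (camera adjusted p = 1.07e-14, and adjusted p = 0.117 with an estimated correlation). Endoplasmic reticulum protein mRNAs were higher in 60 of 62 and lower in 50 with spike-in library sizes, at a median of 1.62 (camera adjusted p = 1.09e-17, and adjusted p = 0.0241 with an estimated correlation). DAD1 was at 2.97, SDF2L1, a lumenal chaperone cofactor, at 2.72 and HSPA5 at 1.57 (SE 0.161, adjusted p = 3.37e-08), which spike-ins turned to -1.01. All 13 mitochondrially encoded mRNAs were higher, at a median of 2.40 (camera adjusted p = 7.25e-07, and adjusted p = 0.165 with an estimated correlation), and with spike-in library sizes 1 was higher and 1 lower. All 34 cytosolic chaperone and cytoskeleton mRNAs were higher, and 19 lower with spike-in library sizes (camera adjusted p = 1.02e-12, and adjusted p = 0.0346 with an estimated correlation). Translation factor mRNAs were higher in 28 of 33, EIF3I at 2.86, and lower in 28 with spike-in library sizes (camera adjusted p = 4.41e-07, and adjusted p = 0.0346 with an estimated correlation). Plasma membrane and lysosomal protein mRNAs were higher in 38 of 45, LAPTM4B at 2.75, and lower in 39 with spike-in library sizes (camera adjusted p = 9.79e-09, and adjusted p = 0.0632 with an estimated correlation). In this comparison each list gave the same numbers adjusted over the list alone as over all genes.

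Zinc finger protein mRNAs were lower in the wash than in the nucleus in 41 of 66 and higher in 3, at a median of -0.68 (camera adjusted p = 6.75e-05, and adjusted p = 0.117 with an estimated correlation). ZNF117, which overlaps another gene, was at -2.22. Intron-retaining RNA-binding protein mRNAs were lower in 30 of 44 and higher in 9 (camera adjusted p = 0.00196, and adjusted p = 0.244 with an estimated correlation), with NKTR at -2.74 (-2.42 within prefix 1, -3.29 within prefix 2) and PNISR at -2.19. That list changed direction with gene-body counts (camera adjusted p = 0.315). Nuclear long noncoding RNAs were lower in 12 of 15 and higher in 3 (camera adjusted p = 0.00676, adjusted p = 0.127 with an estimated correlation, 0.352 with gene-body counts). Small nuclear RNAs were lower in 10 of 14 (camera adjusted p = 0.0644, 0.0275 with the replicate number as a block, and adjusted p = 0.506 with an estimated correlation). edgeR called 11490 genes, 5849 higher and 5641 lower, with 9816 within prefix 1 and 11342 within prefix 2. Higher calls made up 50.9%, 25.7% without a composition factor, 40.5% with DESeq2 and 0.1% with spike-in library sizes (19 higher, 14908 lower). TFRC, at 0.53 (adjusted p = 0.0398), was not called with RLE factors (0.41) or DESeq2 (0.42), nor without wash replicate 1 (0.50) or 2 (0.37) or nucleus replicate 2 (0.53), 3 (0.49) or 4 (0.45), and was at -0.12 without a composition factor. HBG1, at 0.93, was at 0.27 without that factor and at -0.71 with gene-body counts.

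**Figure D3:**
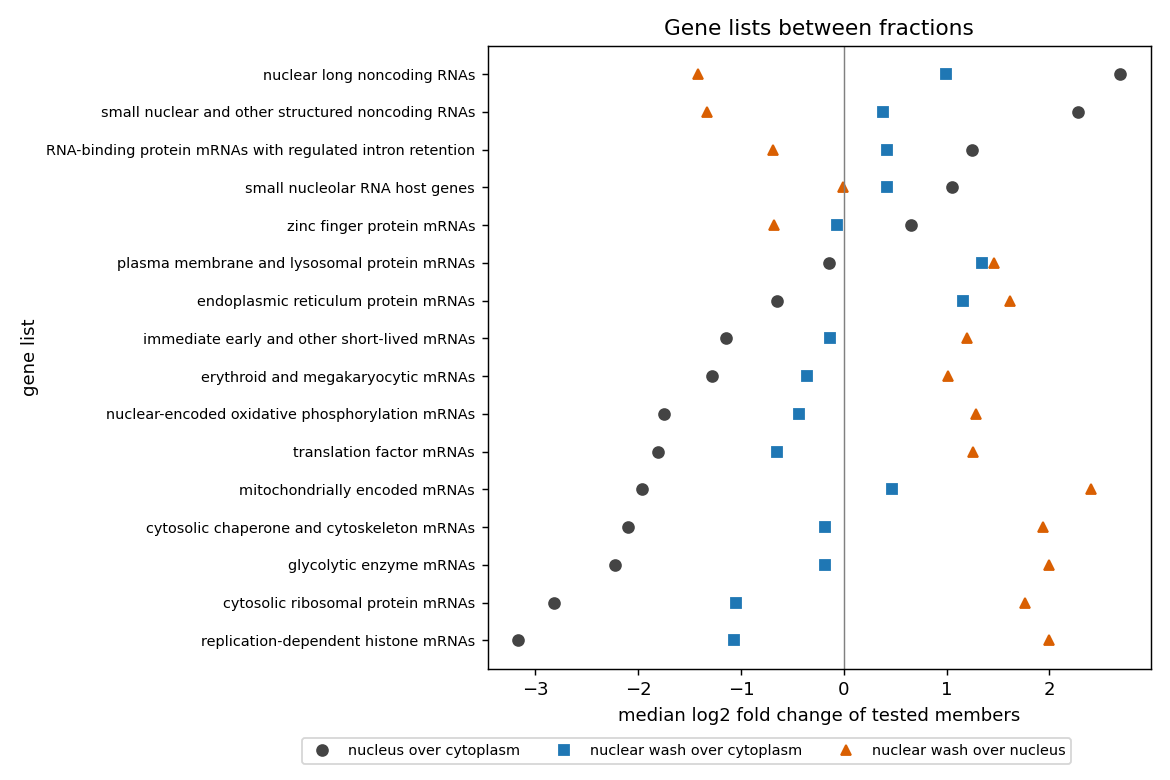
Median log2 fold change of 16 gene lists for nucleus over cytoplasm, nuclear wash over cytoplasm and nuclear wash over nucleus, relative to the typical gene (4 libraries per group). The endoplasmic reticulum list lies at -0.65, 1.16 and 1.62 and the ribosomal protein list at -2.82, -1.05 and 1.76, and with library sizes from spike-ins the wash medians become -2.01 and -0.91 for the reticulum and -4.23 and -0.8 for ribosomal proteins, the other lists with a positive wash median also turning.

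Some transcripts were higher in the wash than in both cytoplasm and nucleus. CALR, the reticulum chaperone calreticulin (ENSG00000179218, chromosome 19, 12938578 to 12944489), was at 2677 ± 319 CPM in the wash, 713.2 ± 98.6 in the cytoplasm and 440.7 ± 14.7 in the nucleus (1.91 and 2.60 on the log2 scale, n = 4 per group). MT-ND6 (ENSG00000198695, mitochondrial genome, 14149 to 14673) was at 4083 ± 681 against 591.6 and 812.2 CPM (2.79 and 2.33), and MT-ND5 at 2.06 and 2.45. LAMP2, a lysosomal membrane protein, was at 2.08 and 2.08, the secreted glycoprotein SPARC at 1.91 and 3.15, and the disulfide isomerase PDIA4 at 2.00 and 1.90. Lower than in both was ZNF480 at 21.29 ± 9.5 CPM against 53.61 and 54.32 (-1.33 and -1.35), USP16 at -1.11 and -1.28, CEP70 at -1.27 and -1.09 and UBE2Q2 at -1.03 and -1.05. The noncoding RNA FIRRE was at -0.96 and -1.42, and its difference from the cytoplasm was -0.02 with gene-body counts.

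The joint edgeR test called 872 genes higher in the wash than in both, 389 of them by at least 2-fold, and 46 lower, 8 by at least 2-fold. Both contrasts use the same wash libraries. In 20 simulations with all fractions drawn from the wash mean, the joint test called 0 genes in either direction. Genes alike in the wash and in only a single other fraction were not simulated. The simulations therefore do not give the rate of false calls among such genes. Called higher in both contrasts separately were 1251 genes, fewer than the 1334.9 that independent lists of 3638 and 5849 genes would share, and called lower 435 against 1208.5. With the wash libraries divided between the contrasts, 639 or 621 genes were higher and 0 or 1 lower. The higher set held 593 genes within prefix 1, 984 within prefix 2 and 328 without a composition factor. With spike-in library sizes edgeR called 0 higher, also at an unadjusted p under 0.05. The lower set was less stable, with 165 genes under a replicate block, 225 within prefix 2, and 0 within prefix 1, where 422 passed an unadjusted p under 0.05, and with 470 without a composition factor and 13807 with spike-in library sizes. Its size was 23, 18, 22 and 23 without cytoplasm replicate 1, 2, 3 or 4, 72, 10 and 12 without wash replicate 2, 3 or 4, and 26 without nucleus replicate 2.

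Against whole cells, the cytoplasm held more of NME2, a nucleoside diphosphate kinase that overlaps a read-through gene (1.46), and of the cytokine MIF (1.36), and less of FRMD5 (-4.92). In the nucleus RN7SL2 was at -4.46, H4C3 at -4.04 and SNORA20, which lies inside TCP1, at 2.37. In the wash MT-TN was at 3.27 and DBN1 at 2.25, both turning with spike-in library sizes (-1.10 and -2.14), and PGGHG was at -2.65. Ribosomal protein mRNAs were higher in the cytoplasm in 70 of 79, or 71 adjusted over the list alone, at a median of 0.82 that spike-ins turned to -0.43 (camera adjusted p = 1.58e-17, and adjusted p = 0.126 with an estimated correlation). They were lower in the nucleus in 73 of 79, also adjusted over the list alone (camera adjusted p = 3.97e-25, and adjusted p = 0.0669 with an estimated correlation). Endoplasmic reticulum protein mRNAs were higher in the wash in 55 of 62, or 58 adjusted over the list alone, although all 62 were lower with spike-in library sizes (camera adjusted p = 2.65e-37, and adjusted p = 0.00102 with an estimated correlation). Plasma membrane and lysosomal ones were higher in 40 of 45, or 42 adjusted over the list alone, although all 45 were lower with spike-in library sizes (camera adjusted p = 3.28e-24, and adjusted p = 0.00555 with an estimated correlation).

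Calls against whole cells numbered 7962 for the cytoplasm (3557 higher, 4405 lower, and 215 against 3263 at 2-fold or more), 8755 for the nucleus (4132 and 4623) and 5477 for the wash (2335 and 3142). Within prefix 1 and prefix 2 the numbers were 6024 and 7876, 7271 and 7349, and 3484 and 5908. The share of higher calls was 44.7, 47.2 and 42.6%, but 20, 70.1 and 15.9% without a composition factor, and 0% in all 3 with spike-in library sizes. The median gene was at 0, 0.04 and -0.1, at -1.24, -1.83 and -4.51 with spike-ins, and at -0.24, 0.41 and -0.4 without a factor. For the nucleus the share was also 58.1% with RLE factors, where the median gene was at 0.2, 55.8% with DESeq2, and 35.6% without the low-count filter. For the wash it was 54.7% in a fit of these 2 groups alone and 53.2% with gene-body counts, which gave 53.3% for the cytoplasm.

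As a mixture of the fraction profiles, whole cells had weights of 55.61% ± 1.11 for the cytoplasm, 33.64% ± 3.35 for the nucleus and 10.74% ± 2.68 for the wash (SD, n = 4), with 3.88% of the weighted variance left. With gene-body counts the nuclear weight was 60.53%. The wash as a mixture of cytoplasm and nucleus had a nuclear weight of 28.15% ± 7.8 (SD, n = 4), and 23.28% of its variance was left. That weight was 35.39 and 34.4% in the libraries of prefix 1, 21.7 and 21.12% in those of prefix 2, and 14.11% on average without weighting of genes.

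Large differences between the undepleted and the depleted wash were those of mitochondrial 12S rRNA and of small structured RNAs. MT-RNR1, the 12S rRNA (ENSG00000211459, mitochondrial genome, 648 to 1601), was at 100100 ± 22700 CPM (n = 3) without depletion and 82.1 ± 60.2 (n = 4) with it (log2 fold change 10.25, SE 0.587, adjusted p = 3.25e-06). The spliceosomal RNA RNU4-2 (ENSG00000202538, chromosome 12, 120291763 to 120291903) was at 191.1 ± 51.3 against 3.537 CPM (5.79) and its copy RNU4-1 at 5.31. RNA5SP429, a 5S pseudogene inside CDH1, was at 7.16. Small nuclear and other structured RNAs were higher in 9 of 14, or 11 adjusted over the list alone, at a median of 3.33 (camera adjusted p = 2e-09, and adjusted p = 0.473 with an estimated correlation). Some mRNAs were higher too, with RPS15 at 834.5 against 77.47 CPM (3.43, adjusted p = 6.19e-06), RPS27 at 3.85, the respiratory subunit NDUFS5 at 3.11, the globin HBA1 at 3.32 and the myosin MYH9 at 1.28. MT-TN (-3.67), the pseudogene SNRPGP10 (-2.55) and RPS21 (-1.39) were lower.

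Ribosomal protein mRNAs were higher without depletion in 38 of 79 and lower in 2, or 40 and 7 adjusted over the list alone. Their median was 0.51 (camera adjusted p = 4.75e-09, and adjusted p = 0.473 with an estimated correlation). It was 0.28 with spike-in library sizes and 0.01 without a composition factor, where 20 were higher and 17 lower. Histone mRNAs were higher in 20 of 42 and lower in none, or 23 and 2 adjusted over the list alone, at a median of 0.64 that was 0.13 without a composition factor (9 higher, 4 lower), with H2AC16 at 2.98 and H4C4 at 1.92 (camera adjusted p = 5.39e-08, and adjusted p = 0.473 with an estimated correlation). Oxidative phosphorylation mRNAs were higher in 22 of 71, or 27 adjusted over the list alone, at a median of 0.40 that was -0.09 without a composition factor, where 11 were higher and 14 lower (camera adjusted p = 3.03e-05, and adjusted p = 0.499 with an estimated correlation). Mitochondrially encoded mRNAs were higher in 7 of 13, or 10 adjusted over the list alone (camera adjusted p = 9.05e-05, and adjusted p = 0.499 with an estimated correlation). MT-ND1 was at 1.49 and MT-ND4 at 1.45, with MT-ND3 lower at -0.81. Endoplasmic reticulum protein mRNAs were higher in 4 of 62 and lower in 4, or 5 and 5 adjusted over the list alone (median 0.01, -0.49 without a composition factor, where 0 were higher and 29 lower, camera adjusted p = 0.894). HSPA5 was at -0.02 (adjusted p = 0.951), GAPDH at -0.26 (adjusted p = 0.272), ACTB at 0.24 (adjusted p = 0.309) and MALAT1 at -0.36 (adjusted p = 0.706). Without a composition factor, where the median gene was at -0.55 (-0.04 with it and -0.26 with spike-ins), HSPA5 (-0.52) and GAPDH (-0.75) were called lower, and a block by column prefix over the 3 matched depleted libraries also called GAPDH (-0.31, adjusted p = 0.00977, and adjusted p = 0.179 in these libraries without the block).

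edgeR called 1290 of 11627 genes between undepleted and depleted wash, 901 higher and 389 lower, 551 and 150 by at least 2-fold. With only the 3 depleted libraries whose prefixes match it called 1492 of 11744, and with the column prefix as a block in these it called 3786. Higher calls were 69.8%, against 10.1% without a composition factor, 51.1% without the low-count filter and 51.3% with the block, so the direction of small changes is open. The count was 768 without depleted replicate 2, 799 without depleted replicate 3, and 467 and 458 without undepleted replicate 2 and 3. NEAT1 (-0.81, adjusted p = 0.0191) was not called without undepleted replicate 2 (adjusted p = 0.118) or 3 (adjusted p = 0.112). A fit within a prefix was not made, since prefix 1 holds 1 undepleted library.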

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

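Chosen only after the result was seen were the tests of nuclear RNA mixed into the wash and of a batch acting on every fraction, the check at 50 CPM, the intervals of paired changes, and the fits and tests within column prefixes. So were the paired tests of shares. Among 248 groups of 4 libraries, 20 held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20. By share of mitochondrially encoded mRNA these were whole-cell replicate 4 at 4.76% (others 3.98 to 4.1) and wash replicate 2 at 6.41% (8.19 to 8.45). In the cytoplasm they were, in CPM, MALAT1 in replicate 3 at 2532 (3313 to 3373), TMEM14EP in replicate 1 at 0.3946, LINC01028 in replicate 4 at 0.1553, H4C3 in replicate 3 at 609.5 (319.2 to 367.1), ARGLU1 in replicate 4 at 37.9 and FIRRE in replicate 2 at 30.21. In the nucleus they were all in replicate 1, with MT-CO2 at 542.3 CPM (249.9 to 283.4), EPCAM at 53.96, MT-ND6 at 1027 (723 to 755.6) and MT-ND5 at 3833 (2487 to 2594). In the wash they were DBN1 in replicate 1 at 547.9 CPM (248.8 to 284.7), IGF2R, COL1A2 and MT-ND5 in replicate 2 at 723.9, 34.53 and 13640, and NORAD in replicate 4 at 362.1. In the fit of wash libraries they were RNA5SP429 in replicate 4 at 2.932 CPM, RPS27 in replicate 1 at 25.37 (10.32 to 12.31) and HSPA5 in replicate 2 at 715.6 (987.4 to 1034).

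A test of the difference between prefix 1 and prefix 2 libraries found unlike fold changes for 68 genes in nucleus over cytoplasm, 289 in wash over cytoplasm and 25 in wash over nucleus. In the first the log2 fold change was larger in prefix 1 for 63 genes, in the second for 253 and in the third for 19. Among 101 values of named genes tested, with some genes in several contrasts, 8 differed (edgeR adjusted p from 3.66e-05 to 0.0497). These differences, prefix 1 minus prefix 2 in log2, were 1.054 for RPS2 and 1.205 for MT-ND3 in nucleus over cytoplasm, and 1.747 for MALAT1, 1.032 for ARGLU1, 0.728 for IQGAP1 and 0.778 for MT-ND3 in wash over cytoplasm. In wash over nucleus they were 0.87 for NKTR and 1.515 for MALAT1.

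mRNAs of the reticulum and plasma membrane lists were higher in the wash than in the cytoplasm relative to the typical gene, at a median of 1.251 over 107 members. Transcript length did not account for it, since the median was 1.19 (95% bootstrap interval 1.087 to 1.349) after a length trend over the other genes was subtracted. Neither, on this scaling, did nuclear RNA mixed into cytoplasmic RNA, since 66.4% of members (71 of 107, exact 95% interval 56.6 to 75.2) were higher than in both fractions. The share was 5.47% over all genes. Without a composition factor 328 genes passed that test instead of 872, and the share of members was not computed there. Nor did a difference between prefixes account for it, the lower of the prefix medians being 1.18 (interval 1.063 to 1.318). These intervals treat members as independent and hold no spread between libraries. A candidate explanation that remains, as a hypothesis, is that RNA bound to membranes around the nucleus enters the wash, for which the design holds no separate fraction. It concerns an excess over the typical gene and not an amount of RNA. Over the median gene the lists stayed 1.09 to 1.11 and 1.25 to 1.3 higher with TMM, RLE, no factor and spike-ins. The sign of the medians and the test against both fractions do rest on the scaling. With spike-in library sizes the medians were -2.01 and -1.86, and 0 genes were higher than in both.

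Wash replicates 1 and 2 held more counts on 3190 genes with at least 4-fold more in nucleus than cytoplasm (3.98 and 3.86% of counts) than replicates 3 and 4 (2.02 and 1.88%). A batch acting equally on every fraction is argued against. The ratio of any prefix 1 to any prefix 2 library was at least 1.914 in the wash. It was 1.083 to 1.178 in the cytoplasm, 1.044 to 1.153 in the nucleus and 0.873 to 1.074 in whole cells. Every prefix 1 library was thus also higher in cytoplasm and nucleus, so a smaller shift shared with these fractions is not excluded. Nuclear contents carried over in different amounts cannot be told apart from other causes: over the 3189 genes without MALAT1 the median log2 ratio was 0.25 (interval 0.222 to 0.276), under the bound of 0.5 set beforehand, but that bound was wrong for genes of few counts, which a pseudocount of 0.5 pulls to 0, and the 73 genes of at least 50 CPM were at 0.623 (interval 0.48 to 0.698), a check made after the result was seen. MALAT1 alone had a share 3.945 times higher, and without it the ratio of shares was 1.391 to 1.633. The undepleted library of prefix 1 also held more (3.05% against 1.39 and 1.32%), and no biological explanation was tested, as the labels name no difference between these libraries.

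Ribosomal protein mRNAs were higher in the undepleted than in the depleted wash relative to the typical gene, at a median of 0.509 (interval 0.244 to 0.838, 79 members), whereas without a composition factor, which puts the median gene at -0.55, their median was 0.01, with 20 higher and 17 lower. Length did not account for it, with a median of 0.54 after the trend was subtracted and a paired change of 0.029 (interval -0.087 to 0.12), where an effect of length as the cause would take away at least 0.255, nor did fewer counts, with 0.51 after the depleted libraries were thinned (change 0.004, interval -0.052 to 0.045, 37 of 77 members higher). The intervals of these medians alone (from 0.217 and 0.257) reach down to about 0.255, so the verdict rests on the paired changes, which were added later. Mitochondrial and ribosomal RNA taking more of the counts stays open as a cause, because leaving these genes out (0.59 over 78 members, paired change 0.011) hardly moved any gene once libraries were scaled for composition. Cross-reaction of the depletion step with some mRNAs may remain as a hypothesis that these files cannot test, and no biological explanation was tested.

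In each of the 7 comparisons of groups only 1 of 35 splits, the real one, gave as many genes, the smallest share that 35 splits can reach. The other splits mix libraries of both groups, which raises the spread estimated in them. Their low counts therefore do not measure how many calls are false, and chance division is not excluded by them. The highest count of another split was 0 against 12236 for nucleus and cytoplasm, 1 against 7053 for wash and cytoplasm, a split that follows the column prefix, and 0 against 11490 for wash and nucleus. It was 0 against 7962 for cytoplasm, 0 against 8755 for nucleus and 37 against 5477 for wash, each with whole cells, and 391 against 1290 for undepleted and depleted wash, where the split by prefix gave 385. Splits that part as many same-numbered pairs as the real one gave at most 0 genes, except that of 391. For the joint tests 1 of 100 drawn splits, the real one, gave as many, with 872 and 46 genes against 0 and 0, under the same limit.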

How the results depend on the processing

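Fits within the libraries of one column prefix were chosen after the data were seen. Of 378 alternatives for counts, shares and weights, 330 were rated the same. Shares and weights had to keep the side of the threshold and the direction, or stay within the spread. Counts of calls had to stay within 1.5 times the main total, and their direction was not rated. The 330 thus include wash and nucleus with spike-in library sizes, at 14927 calls, 19 higher and 14908 lower. Of 3432 values of single genes and lists under an alternative, 3232 kept direction and call, 112 lost the call, 37 gained it and 51 reversed. The cause was not tested unless it is named here. Of simulated 2-fold changes 42.9% were recovered between the wash libraries, where the part of depth was not separated from that of spread and library number.

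With library sizes from the spike-ins every gene is shifted by construction (the median gene then lies at -3.1 for wash over cytoplasm, -2.47 for wash over nucleus), which is the cause of the changes under it, and as the amount of spike-in per sample is not given these cannot be read as changes in amount of RNA. Values are given as fitted, and after the median of all genes is subtracted 153 of 154 had the sign of the main value. The calls were 14869 for wash and cytoplasm, 14700 for cytoplasm, 13771 for nucleus and 15940 for wash against whole cells, 0 higher and 13807 lower than both, and 471 for undepleted wash. Log2 values that reversed in nucleus over cytoplasm were HSPA5 -0.116 and MYB -0.247. In wash over cytoplasm they were HSPA5 -1.128, HYOU1 -1.187, IGF2R -1.044, APLP2 -1.062, TFRC -1.772, FLNA -2.02, MT-ND6 -0.392, MT-ND3 -0.357, MT-CO1 -2.515, SRRM2 -1.192, ARGLU1 -1.033, MALAT1 -1.174, NEAT1 -1.399, PTPRC -1.527, EPCAM -1.783, COL1A2 -0.578, FN1 -0.984, LAMP2 -1.098, MT-ND5 -1.096, SPARC -1.29, CALR -1.283 and PDIA4 -1.182. In wash over nucleus they were NORAD -0.59, HSPA5 -1.012, TFRC -1.939, HBG1 -1.592, GATA1 -0.846, KRT19 -0.2, EPCAM -0.607, MT-ND6 -0.231, LAMP2 -0.475, MT-ND5 -0.083, MT-ND3 -0.548 and PDIA4 -0.64. In wash over whole cells they were MT-TN -1.098 and DBN1 -2.144.

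Gene-body counts add intronic reads and gave 12051 calls for cytoplasm and whole cells. They reversed MT-ND3 (-0.692), HBG1 (2.563) and HSPA5 (-0.958) in nucleus over cytoplasm, HBG1 (1.853) in wash over cytoplasm, and NEAT1 (0.004) and HBG1 (-0.71) in wash over nucleus. MT-ND3 and NEAT1 are annotated as exon over their whole length (346 and 22767 bases), so reads in their own introns cannot explain this. Intronic reads also raise library totals unequally, in replicate 1 from 1826538 to 6390215 in the nucleus and from 5561300 to 6339070 in the cytoplasm. A shift of the baseline may thus have moved these values, which was not tested. Gene-body counts also reversed lists, by camera adjusted p the intron-retaining list (0.315) in wash over nucleus, small nucleolar RNA host genes (0.0345) and the intron-retaining list (0.736) in cytoplasm over whole cells, and ribosomal protein (0.0157), translation factor (0.0149) and histone (0.00178) lists in wash over whole cells. Lists called numbered 14 for wash over whole cells and 11 for undepleted wash. With these counts the mitochondrial share differed by 2.00 points for wash and cytoplasm, no longer past the threshold, and 1.71 for cytoplasm and whole cells, now past it, with mitochondrial rRNA likewise by 4.28 and 3.78, and the nuclear weight of whole cells was 60.53%. That weight was 29.24% unweighted and 37.01% from cytoplasm and nucleus alone, and the weight of the wash was 14.11% unweighted. The 2.00 and 1.71 points also carry the unlike intronic share of the gene-body totals.

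Without a composition factor 328 genes were higher and 470 lower than both, 3971 were called for undepleted wash, and TFRC in wash over nucleus reversed (-0.121). RLE factors gave 70 genes lower than both, no low-count filter 26, and 1987 for undepleted wash. With the replicate number as a block 165 genes were lower than both, and with the column prefix as a block 3786 were called for undepleted wash against the 3 matched depleted libraries (1492 without the block). The block also gained 6 list calls, the small nuclear RNA list in 4 comparisons, glycolytic mRNAs in wash over cytoplasm (0.0486) and small nucleolar RNA host genes in nucleus over whole cells (0.0483), and GAPDH in undepleted wash, and among the named genes and lists compared it changed no other call, and no other count of calls by over 1.5 times. Prefix 1 libraries alone gave 3484 calls for wash and whole cells and 0 genes lower than both, and prefix 2 libraries 225.

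With the correlation between genes estimated, lists called were 3 of 13 for nucleus and cytoplasm, 4 of 9 for wash and cytoplasm, 3 of 14 for wash and nucleus, 0 of 11, 3 of 13 and 2 of 9 for cytoplasm, nucleus and wash against whole cells, and 0 of 6 for undepleted wash. Leaving out 1 library at a time gave 12067 to 12536, 6358 to 6809 and 11147 to 12043 genes for the first 3 comparisons, 7050 to 7880, 7810 to 8318 and 4484 to 5458 against whole cells, 742 to 895 higher and 10 to 72 lower than both, and 458 to 1492 for undepleted wash. Of 1210 single-gene values from these fits 8 lost the call and none reversed.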

Other observations

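Permutation tests of ratios in the first paragraph and all values of the second were chosen only after the data were seen. MT-ND6, the mRNA of the mitochondrial light strand, made up a varying part of the mitochondrial RNA. Per 100 counts on heavy-strand mitochondrial mRNAs it had 1.46 ± 0.125 (SD, n = 4) in the cytoplasm, 3.50 ± 0.323 in whole cells, 5.99 ± 0.679 in the nuclear wash and 7.20 ± 0.708 in the nucleus, and 8.49 in the undepleted wash. Wash and cytoplasm differed (two-sided exact permutation test, adjusted p = 0.0343), whereas wash and nucleus did not pass (exact permutation test, p = 0.0857), although the wash was lower in all 4 same-numbered pairs (exact paired permutation test, p = 0.125, the smallest that 4 pairs can give). The 8 light-strand tRNAs had 0.316 counts per 100 in the cytoplasm, 0.326 in whole cells, 0.651 in the wash and 0.967 in the nucleus. Whether reads were assigned by strand is not given in the sources used here, so counts on MT-ND6 and these tRNAs could not be separated from antisense reads. Spike-in counts per 100 human exon counts were 0.217 in whole cells, 0.433 in the cytoplasm, 1.02 in the nucleus and 3.78 ± 0.554 in the wash.

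For 6 genes high in the wash, chosen after their values were seen, the other contrasts are given as values only. Over the cytoplasm the nucleus had SPTBN1 at 3.44, SPTAN1 at 3.49, IQGAP1 at 3.33, MACF1 at 2.5, DBN1 at 1.81 and AHNAK at 1.30 on the log2 scale. Over the nucleus the wash had SPTBN1 at 0.67, IQGAP1 at 0.60, AHNAK at 0.84, DBN1 at 1.71, MACF1 at -0.56 and SPTAN1 at 0.32, which did not pass. With library sizes from the spike-ins the median gene of wash over nucleus lies at -2.47, further from 0 than each of these positive values. Over whole cells the wash held DBN1 at 2.25, SPTBN1 at 1.68, IQGAP1 at 1.59, AHNAK at 1.17, SPTAN1 at 1.11 and MACF1 at 0.20, the last not called. There spike-ins put the median gene at -4.51, and all 15940 genes are lower.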
